A study of Homo sapiens with 8 samples.

How the data were processed

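Total RNA of AGS cells, kept in Ham's F-12 medium with 10% fetal bovine serum per the labels, was sequenced after 4 hours with Helicobacter, Fusobacterium or Neisseria and from untreated cells. The labels give 2 libraries per group, numbered 2 and 3 for each bacterium and 1 and 2 for the untreated cells, and name an RNeasy kit for the extraction. All 8 libraries were used and every column of the deposited file belongs to a library.

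The deposited file holds whole-number total counts per Ensembl gene identifier, which the authors made from paired reads, per the file headers, aligned to hg19 (GRCh37), per the labels. The deposited RPKM values were made by the authors by dividing counts by gene length and a library total. The deposited TPM values were made by the authors by dividing by length and rescaling each library to a common sum, per the file headers. Another set of deposited columns, headed CPM, holds a signal that the authors made by dividing each count by 1 factor per library, and these columns sum to between 948659 and 1052410, so the factor is an adjusted library size. The aligner, the counting program, the versions, the strand setting and any filter of the authors are not given in the sources used here. Counts of overlapping or antisense genes, of readthrough genes and of near-identical copies (histones, HSPA1A and HSPA1B, AKR1C, CEACAM, SPRR and metallothionein genes) may therefore be shared. Only the counts were used for the tests. The CPM in the text were computed from them and are not the deposited columns.

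Coordinates are those of the deposited file on GRCh37. GENCODE 29 (on GRCh38) was used for gene biotypes, lengths and GC content, matched by identifier without version for 52338 of 57773 genes. Totals ranged from 17167078 to 26380033 counts per library, a 1.54-fold range, and 3 counts per library were taken as the floor for a gene at 0, averaged over the group. Floors and the exact (Clopper-Pearson, 95%) intervals of count ratios cover counting error only, since PCR copies without molecular identifiers are not independent molecules.

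Differential expression was tested with edgeR 4.0.16 (R 4.3.3, limma 3.58.1) on 13756 genes kept by filterByExpr with a minimum count of 10. The model had TMM factors, robust dispersion and quasi-likelihood fits (estimateDisp, glmQLFit, glmQLFTest) and all 8 libraries in 1 fit with 4 groups and 4 residual degrees of freedom. Benjamini-Hochberg adjustment ran over all tested genes within each of 6 comparisons, 3 with untreated cells and 3 between bacteria, and a gene was called at an adjusted p under 0.05. Standard errors are the log2 fold change divided by the square root of the F statistic. Quasi-likelihood tests are two-sided. CPM were computed with TMM-adjusted library sizes. Principal components were taken from log2 CPM with a prior count of 2.

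Before the data were examined, 30 gene lists were fixed for this tissue and treatment, including markers of leukocytes, fibroblasts and endothelium, and all other choices named here except those said to be made later. The 28 lists with at least 5 tested members were tested with camera (preset correlation 0.01) against all other tested genes, adjusted over the lists within a comparison, and again with an estimated correlation and with fry. With an estimated correlation camera uses the 4 residual degrees of freedom, which by itself raises its p-values. A list can therefore fail there without correlated genes. Member counts were also adjusted over the list alone. A further 6 lists were written after the values had been seen. The rule for named genes took, per comparison with untreated cells, protein-coding genes with a symbol, an adjusted p under 0.05, a mean of at least 1 CPM in the higher group and both treated libraries beyond both untreated ones, the 10 largest rises and the 6 largest falls. Between bacteria it took 5 in each direction, and in each list the up to 4 members with the smallest p, with their values in the other comparisons.

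The test was run on simulated data of 13756 genes with the same group sizes and a spread set by the trended dispersion. It recovered 78%, 75% and 78% of genes shifted by a log2 change of 0.5 in the Helicobacter, Fusobacterium and Neisseria comparisons, and 93%, 91% and 95% of those shifted by 1. Of unshifted genes it called 0.106%, 0.0377% and 0.0829%. Only 100 genes were shifted by each size, all with a mean above 1 CPM. These rates therefore do not cover low genes, a gene's own spread, or comparisons with as many changes as the data. Of 20 random lists camera called 0 in each simulated comparison. The genes were simulated independently of each other, so this does not check the preset correlation for lists of correlated genes. Replicate libraries differed by more than counting error, with a mean chi-square per gene of 2.73 in untreated cells, 2.73 with Helicobacter, 4.60 with Fusobacterium and 3.76 with Neisseria. Deviations of replicates 2 and 3 from their group mean correlated across 9588 genes at -0.034 between Helicobacter and Fusobacterium, 0.079 between Helicobacter and Neisseria and 0.159 between Fusobacterium and Neisseria.

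Alternatives covered DESeq2 size factors, upper-quartile factors, library size only, the DESeq2 1.42.0 Wald test, limma-voom, the legacy quasi-likelihood fit, no filter and a stricter filter on low counts, only the 4 libraries compared, a 2-fold minimum, each library left out in turn, and a replicate block between bacteria. Chosen after the data were seen were a replicate block of all 8 libraries and a split of the untreated libraries between the bacteria. Overlaps between the responses were set beside 20 simulations with no effect that share the untreated libraries. Groups of 2 libraries are too small for a test of outlying samples or for counting other splits. Tables and figures were made with Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, statsmodels 0.14.6 and matplotlib 3.10.9.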

Results

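RNA sequencing measured gene expression in AGS cells, a human gastric adenocarcinoma line with epithelial features, after contact with bacteria of 3 genera. The labels name the bacteria as Helicobacter, Fusobacterium and Neisseria, with the short forms Hp, Fn and Nc in the sample titles. They give a contact time of 4 hours. Neither the species or strain, nor the number of bacteria per cell, nor a mock treatment of the untreated cells is spelled out in the labels. Helicobacter is a colonist of the stomach, while Fusobacterium and Neisseria are common in the mouth. The design asks how the transcriptome of gastric epithelial cells responds to each. There were 8 libraries in 4 groups, with 2 libraries of untreated cells (replicates 1 and 2) and 2 for each bacterium (replicates 2 and 3). The untreated libraries held 17967631 and 23823424 gene counts, the Helicobacter libraries 21407299 and 22670213, the Fusobacterium libraries 26380033 and 17167078, and the Neisseria libraries 24633038 and 18494692. Levels are given as CPM, counts relative to the library size adjusted for composition, and 3 counts in each untreated library came to a mean of 0.144 CPM. Such floors and the intervals of ratios cover counting error only. Of 57773 genes listed in the deposited file, 21884 had a count in some library and 13756 were expressed highly enough to be tested. The labels do not say whether the libraries of a group came from separate cultures, so the p-values measure only the spread between these samples, which may be technical. That spread was small, with a common biological coefficient of variation of 4.17%. Mitochondrial transcripts took 3.17% and 3.07% of the counts in the untreated libraries, 2.32% and 2.22% with Helicobacter, 2.60% and 2.66% with Fusobacterium, and 2.48% and 2.58% with Neisseria.

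The libraries of each group lay close together in a principal component analysis of log2 CPM and the 4 groups lay apart. The component with the largest share, 63.4% of the variance, parted the Fusobacterium libraries from all others. The next component, with 15.7%, placed the Neisseria libraries at its far end, and the component after it, with 8.88%, parted the Helicobacter libraries from the untreated ones.

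**Figure D1:**
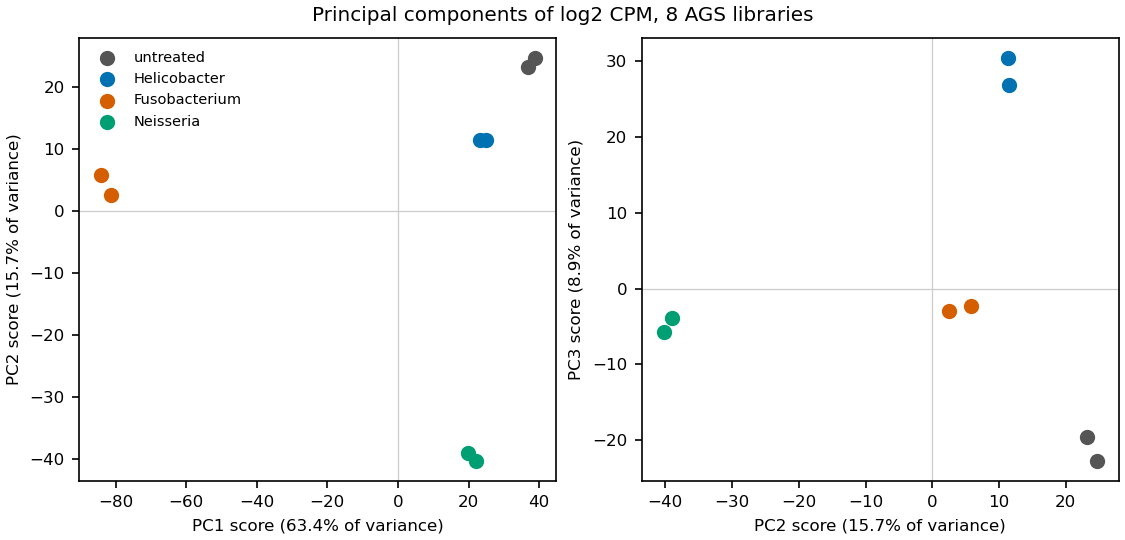
Scores of the 8 libraries on the leading principal components of log2 CPM (arbitrary units), with PC1 (63.4% of the variance) against PC2 (15.7%) on the left and PC2 against PC3 (8.88%) on the right. Each point is a library, coloured by group, and the 2 libraries of each group fall next to each other.

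The comparison of Helicobacter-treated with untreated cells asks what contact with this bacterium changes in gastric cells within 4 hours. The largest rises included the matrix proteases MMP1 and MMP10, CYP1A1, UBD and small proline-rich proteins. MMP1, the interstitial collagenase (ENSG00000196611, chromosome 11, 102660651 to 102668891, GRCh37), rose from 7.51 ± 0.658 to 201 ± 8.74 CPM (SD, n = 2 each), a log2 fold change of 4.76 ± 0.19 (SE) with an edgeR adjusted p of 1.24e-05. CYP1A1, a cytochrome P450 enzyme induced through the aryl hydrocarbon receptor (ENSG00000140465, chromosome 15, 75011883 to 75017951), rose from 2.88 ± 0.147 to 76.4 ± 5.99 CPM, a log2 fold change of 4.73 ± 0.13 (edgeR adjusted p = 7.74e-18). The stromelysin MMP10 rose by a log2 fold change of 4.69 ± 0.32 and the ubiquitin-like modifier UBD by 5.49 ± 0.47. Rises were also seen in the costimulatory receptor TNFRSF9 (4.13 ± 0.23), the annexin ANXA10 (4.08 ± 0.55) and the calcium-binding protein S100A3 (4.07 ± 0.29). Of the small proline-rich proteins, which are precursors of the cornified envelope, SPRR1B rose by 4.66 ± 0.41. ANXA10, UBD and SPRR1B had at most 4 counts in either untreated library (means of 0.096, 0.108 and 0.137 CPM). The sizes of their rises therefore rest on few counts. SPRR3, with 0 counts in both untreated libraries and 2.13 ± 0.00494 CPM with Helicobacter, was at least 14.8-fold higher than a floor of 3 counts per untreated library. GZMB, which encodes the protease granzyme B, had 110 counts with Helicobacter against 1 in untreated cells, a ratio of 101 with an exact 95% interval for counting error of 17.7 to 4014. Among the largest falls were the Ras-like GTPase RASD1 (-3.03 ± 0.44), the potassium channel KCNJ13 (-2.92 ± 0.40), the NADPH oxidase NOX1 (-2.73 ± 0.21), and the transcription factors FOSB (-2.51 ± 0.15) and EGR3 (-2.21 ± 0.40).

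Among gene lists fixed before the data were examined, NF-kB targets and chemokines were higher with Helicobacter, with 15 of 34 tested members up and 2 down and a median log2 fold change of 0.48 (0.40 with the members at 0 counts set to their bounds). The camera adjusted p was 3.54e-07, and the adjusted p was 0.0720 with an estimated correlation. TNFAIP3, a feedback inhibitor of NF-kB, rose by 1.17 ± 0.11, RELB and NFKB2, both NF-kB subunits, by 0.92 ± 0.075 and 0.73 ± 0.064, and the transcription factor IRF1 by 0.68 ± 0.079. The chemokine IL8 stood at 8.84 ± 0.267 CPM against 8.02 ± 0.855 in untreated cells, a log2 fold change of 0.15 ± 0.15 that did not pass the test (edgeR adjusted p = 0.452). Cholesterol biosynthesis genes were higher, with 13 of 21 up and 2 down, including CYP51A1 (0.66 ± 0.050), FDPS (0.68 ± 0.061) and SQLE (0.47 ± 0.051). Their camera adjusted p was 2.45e-07, and the adjusted p was 0.275 with an estimated correlation. Of 19 genes of epithelial-mesenchymal transition and matrix remodelling 9 rose and 1 fell (camera adjusted p = 1.98e-13, adjusted p = 0.184 with an estimated correlation), among them the matrilysin MMP7 (3.33 ± 0.23) and CD44 (0.78 ± 0.070). Replication-dependent histones (7 of 12 up, camera adjusted p = 0.00762) and host receptors for bacterial adhesion (6 of 11 up and 3 down, camera adjusted p = 0.0128) also passed. Their adjusted p values were 0.292 and 0.316 with an estimated correlation. CEACAM6 rose by 0.86 ± 0.060 and CEACAM5 by 1.49 ± 0.10, and reads of these related receptors, like those of histone copies, may be split between genes.

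Immediate-early and AP-1 genes, which are transcribed within minutes of growth factor signals, fell, with 21 of 28 down and 3 up and a median of -0.55 (camera adjusted p = 4.54e-17, adjusted p = 0.0720 with an estimated correlation). CYR61 (-1.23 ± 0.087), CTGF (-0.88 ± 0.064) and SRF (-0.82 ± 0.060) were among them. Every member of the G1/S and DNA replication list was lower, 22 of 22, with a median of -0.56 (camera adjusted p = 4.99e-20, adjusted p = 0.0720 with an estimated correlation), for example the helicase subunits MCM4 (-0.74 ± 0.059) and MCM5 (-0.67 ± 0.060) and the licensing factor CDT1 (-0.74 ± 0.061). All 13 mitochondrially encoded mRNAs fell, with a median of -0.52 (camera adjusted p = 5.04e-18, adjusted p = 0.0720 with an estimated correlation). The mitochondrial share of counts includes these mRNAs, so its lower value is no separate observation. That share was below the untreated values in every treated library. Cytosolic ribosomal protein genes fell in 25 of 30 cases with a median of -0.21 (camera adjusted p = 2.45e-07, adjusted p = 0.444 with an estimated correlation). Of 25 genes of the actin cytoskeleton and of the transcription factor SRF 11 fell and 0 rose, with a median of -0.26 (-0.14 with bounds), including ZYX (-0.93 ± 0.051), CNN2 (-0.85 ± 0.053) and VCL (-0.59 ± 0.052). That list had a camera adjusted p of 5.72e-07 and an adjusted p of 0.184 with an estimated correlation. Also lower were the lists of Wnt/beta-catenin targets (8 of 14 down, DKK1 -0.89 ± 0.063) and heat shock genes (6 of 14 down and 1 up, HSPA8 -0.71 ± 0.051). The same held for interferon-stimulated genes (10 of 25 down and 3 up, OAS2 -1.21 ± 0.12), MAPK feedback genes (10 of 21 down and 3 up, DUSP1 -0.93 ± 0.11) and tight and adherens junction genes (9 of 20 down and 3 up, CLDN2 -1.35 ± 0.086). Their camera adjusted p values were 1.32e-04, 0.00310, 0.0103, 0.0142 and 0.0395 in that order. With an estimated correlation the adjusted p values were 0.0720, 0.184, 0.275, 0.184 and 0.184.

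The other 13 tested lists did not pass in this comparison. They included hypoxia targets (6 of 21 up and 3 down), ATF4 and unfolded protein response genes (4 of 23 up and 5 down), p53 targets (1 of 21 up and 4 down) and NRF2 genes (6 of 18 up and 6 down). They also included TGF-beta targets (1 of 11 up and 4 down), G2/M genes (7 of 21 up and 3 down), and apoptosis genes (5 of 18 up and 5 down). The others were gastric and mucin genes (4 of 15 up and 2 down), pattern recognition receptors (4 of 13 up and 1 down), antimicrobial genes (5 of 8 up and 0 down), glycolysis (5 of 16 up and 1 down) and the leukocyte and fibroblast markers. Their lowest camera adjusted p was 0.112 and their highest 0.776. Markers of other cell types were also read, with 3 of 6 leukocyte markers up (camera adjusted p = 0.133) and 1 of 5 fibroblast markers up and 1 down (camera adjusted p = 0.766). Both tested endothelial markers were up, VWF by 1.36 ± 0.33 and ESAM by 0.46 ± 0.11. The metallothionein list had 4 tested members, too few for a list test, of which 3 rose, MT2A by 0.73 ± 0.092. Adjusted over the list alone, the counts differed for MAPK feedback genes (11 down), interferon-stimulated genes (12 down), ATF4 genes (5 up), heat shock genes (2 up), NRF2 genes (7 down), actin genes (1 up and 12 down), junction genes (11 down) and Wnt targets (9 down). They also differed for G2/M genes (8 up and 4 down), apoptosis genes (7 up), gastric genes (5 up), pattern recognition receptors (2 down), adhesion receptors (4 down), ribosomal proteins (28 down) and histones (8 up), and were the same for the other lists. Over all genes 4887 of 13756 changed, 2484 higher and 2403 lower (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05). Of these 388 changed at least 2-fold, 265 higher and 123 lower. Scaled by library size only, the calls were 3140 higher and 1886 lower. Without untreated replicate 2 the number of changed genes was 3147, and with the replicate number as a block, chosen after the data were seen, it was 3033. Of the 15 lists that passed camera with the preset correlation, 0 passed with an estimated correlation, where the lowest adjusted p was 0.0720 and 7 lists had an unadjusted p under 0.05. That version also rests on the 4 residual degrees of freedom, so these losses are not evidence of correlated genes alone. For Wnt targets the estimated correlation was -0.036, below the preset 0.01, yet the unadjusted camera p went from 4.24e-05 to 0.0121. The fry test, which asks whether the genes of a list move in a common direction, passed 20 lists.

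Of the 3 bacteria, Fusobacterium changed the largest number of genes, and its largest rises included genes without counts in untreated AGS cells. CYP1A1 rose from 2.88 ± 0.147 to 1644 ± 9.24 CPM (SD, n = 2 each), a log2 fold change of 9.16 ± 0.10 (SE) or 572-fold (edgeR adjusted p = 2.01e-25). NOVA2, a splicing regulator of neurons (ENSG00000104967, chromosome 19, 46436992 to 46476804), had 0 counts in both untreated libraries and 9.99 ± 0.0353 CPM with Fusobacterium, at least 69.6-fold above a floor of 3 counts per untreated library. By the same floor the ammonium transporter RHCG was at least 62.5-fold higher, the scavenger receptor SCARA5 at least 33.3-fold and the homeobox factor DLX3 at least 32.8-fold. Likewise the hexose transporter SLC2A6 was at least 23.8-fold higher, the filamin-interacting FILIP1 at least 22.4-fold, the nucleotide receptor P2RY2 at least 21.4-fold, the tubulin TUBB4A at least 21.3-fold and the synaptotagmin SYT5 at least 17.2-fold. CLDN2, a pore-forming claudin of tight junctions (ENSG00000165376, chromosome X, 106143394 to 106174091), fell from 167 ± 8.89 to 2.80 ± 0.169 CPM, a log2 fold change of -5.88 ± 0.14 (edgeR adjusted p = 8.89e-13). The receptor phosphatase PTPRO (-5.04 ± 0.47), NOX1 (-4.80 ± 0.29) and the interferon-induced OAS2 (-4.27 ± 0.19) fell too. XAF1, another interferon-induced gene, had 67 counts in untreated cells and 1 with Fusobacterium, a ratio of 65.7 with an exact 95% interval of 11.4 to 2634. An identifier of the mitochondrial ribosomal protein MRPL30 that shares its symbol with another also fell (-4.56 ± 0.98), with counts that may be split between overlapping genes.

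NF-kB targets and chemokines rose with Fusobacterium, with 22 of 34 up and 5 down and a median log2 fold change of 1.32. The camera adjusted p was 1.11e-11, and the call held with an adjusted p of 0.0490 with an estimated correlation. IL8 rose from 8.02 ± 0.855 to 120 ± 7.63 CPM (3.91 ± 0.099), TNFAIP3 by 3.69 ± 0.089 and RELB by 2.19 ± 0.069. Immediate-early and AP-1 genes rose as well, 22 of 28 up and 3 down, with a median of 0.75, a camera adjusted p of 1.69e-06 and an adjusted p of 0.0490 with an estimated correlation. FOS rose by 1.61 ± 0.069, JUNB by 1.07 ± 0.055 and KLF6 by 1.26 ± 0.053. Hypoxia and HIF1 targets were higher in 15 of 21 cases and lower in 2 (camera adjusted p = 7.38e-06, adjusted p = 0.0490 with an estimated correlation), including NDRG1 (2.60 ± 0.060), the glucose transporter SLC2A3 (2.06 ± 0.055) and the lipase inhibitor ANGPTL4 (6.06 ± 0.20). NRF2 and oxidative stress genes were higher in 15 of 18 cases and lower in 2, with SRXN1 at 2.27 ± 0.056, the thioredoxin reductase TXNRD1 at 2.17 ± 0.061 and the ferritin chain FTH1 at 1.62 ± 0.054. Their camera adjusted p was 9.10e-08, and the adjusted p was 0.0527 with an estimated correlation. Of 19 genes of epithelial-mesenchymal transition and matrix remodelling 16 rose and 0 fell, with a median of 1.94 (camera adjusted p = 1.88e-15, adjusted p = 0.0945 with an estimated correlation). The urokinase receptor PLAUR rose by 1.94 ± 0.069. Glycolysis genes (12 of 16 up and 2 down, HK1 3.20 ± 0.077) and actin and SRF genes (15 of 25 up and 7 down, FSCN1 3.97 ± 0.084) passed as higher. So did gastric and mucin genes (8 of 15 up and 3 down, KRT20 5.26 ± 0.23 and SOX2 -1.65 ± 0.071) and apoptosis and pyroptosis genes (11 of 18 up and 5 down). Of the last list the inhibitor of apoptosis BIRC3 rose by 5.88 ± 0.12, the death-promoting BIK and BMF by 2.44 ± 0.066 and 2.05 ± 0.073, and the survival factor BCL2L1 fell (-1.13 ± 0.054). In that order the camera adjusted p values were 0.00302, 0.0221, 0.0236 and 0.0130. With an estimated correlation the adjusted p values were 0.454, 0.445, 0.442 and 0.121.

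All 22 G1/S and DNA replication genes fell with Fusobacterium, with a median of -1.41 (camera adjusted p = 8.79e-23, adjusted p = 0.0490 with an estimated correlation). Thymidylate synthase TYMS fell from 71.6 ± 3.34 to 10.7 ± 0.229 CPM (-2.74 ± 0.083), and MCM5 (-2.12 ± 0.069) and MCM2 (-1.91 ± 0.061) fell as well. Of 21 G2/M genes 17 fell and 1 rose, among them the cyclin CCNB2 (-1.05 ± 0.061) and MKI67 (-0.79 ± 0.055), with a camera adjusted p of 1.94e-04 and an adjusted p of 0.245 with an estimated correlation. Wnt/beta-catenin targets were lower in 10 of 14 cases and higher in 4 (camera adjusted p = 2.40e-05, adjusted p = 0.0490 with an estimated correlation). The pathway inhibitor NKD1 (-2.42 ± 0.067), the stem cell receptor LGR5 (-1.95 ± 0.062) and the ubiquitin ligase RNF43 (-1.08 ± 0.052) fell. Type I interferon-stimulated genes were lower in 17 of 25 cases and higher in 5, with IFIT1 at -1.79 ± 0.074, IFIT3 at -1.79 ± 0.12 and, in the other direction, ISG20 at 2.48 ± 0.083. Targets of p53 (14 of 21 down and 5 up, TP53I3 -1.22 ± 0.069 and GDF15 0.97 ± 0.054) and heat shock genes (9 of 14 down and 4 up, HSPA8 -1.36 ± 0.053) were lower. These 3 lists had camera adjusted p values of 0.0162, 0.0136 and 0.0236, and adjusted p values of 0.245, 0.273 and 0.240 with an estimated correlation.

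Markers of other cell types moved with Fusobacterium. Of 14 listed leukocyte markers 6 had enough counts in these epithelial cells to be tested, and 5 rose and 1 fell, with CORO1A at 4.72 ± 0.11, CSF1R at 4.07 ± 0.15 and CD68 at 3.49 ± 0.14 (camera adjusted p = 1.40e-06, adjusted p = 0.0503 with an estimated correlation). Of 5 fibroblast markers 3 rose, COL1A1 by 2.10 ± 0.069 (camera adjusted p = 0.0677), and the endothelial markers VWF and ESAM rose by 4.05 ± 0.22 and 2.81 ± 0.084. All 4 tested metallothionein and zinc genes rose, MT2A by 3.18 ± 0.081. Junction genes were up in 13 of 20 cases and down in 4, with a median of 0.36, a mean of -0.0045 and no passing test (camera adjusted p = 0.188, direction up). Pattern recognition receptors had a median of -0.021 and a mean of 0.38, 6 up and 4 down of 13 (camera adjusted p = 0.926, direction up), and that median turned to 0.00275 with DESeq2 size factors. The other lists that did not pass (lowest camera adjusted p 0.0677, highest 0.926) included MAPK feedback genes (8 up and 5 down), ATF4 and unfolded protein response genes (11 up and 8 down), and cholesterol biosynthesis (8 up and 3 down). They also included TGF-beta and BMP targets (6 up and 4 down), adhesion receptors (6 up and 3 down), antimicrobial peptides (4 up), ribosomal proteins (4 up and 2 down), mitochondrial mRNAs (8 down) and histones (5 up and 1 down). Adjusted over the list alone, the counts differed for immediate-early genes (23 up), NRF2 genes (3 down), ribosomal proteins (2 up and 1 down) and mitochondrial mRNAs (7 down), and were the same for the others. In all 9551 of 13756 genes changed, 4705 higher and 4846 lower (edgeR adjusted p under 0.05), and 2801 changed at least 2-fold, 1872 higher and 929 lower. Scaled by library size only, the calls were 4134 higher and 5576 lower. Of the 16 lists that passed, 5 passed with an estimated correlation.

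Contact with Neisseria raised the lists of NF-kB targets and of heat shock genes and lowered that of ATF4 pathway genes. CXCL5, a chemokine for neutrophils, had 293 counts with Neisseria against 2 in untreated cells, a ratio of 150 with an exact 95% interval of 41.2 to 1245, and the cytokine LTB had 92 counts against 2, a ratio of 47.1 with an interval of 12.7 to 395. UBD (ENSG00000213886, chromosome 6, 29523292 to 29527702) rose from 0.108 ± 0.153 to 15.7 ± 0.183 CPM (SD, n = 2 each), a log2 fold change of 7.30 ± 0.34 (SE, edgeR adjusted p = 1.28e-14). SPRR1A rose by 5.12 ± 0.25, and the corneodesmosome protein CDSN was at least 10.8-fold and SPRR3 at least 7.57-fold above the floor of 3 counts per untreated library. The keratin-associated protein KRTAP3-1 had 60 counts against 3, a ratio of 20.5 with an interval of 6.68 to 102. ANXA10 rose by 4.49 ± 0.51, CYP1A1 by 4.44 ± 0.13 to 62.8 ± 7.87 CPM, and the receptor adaptor TRAF1 by 4.29 ± 0.31. The ANXA10 value rests on 2 counts in each untreated library. INHBE, an inhibin subunit induced by amino acid and endoplasmic reticulum stress (ENSG00000139269, chromosome 12, 57846106 to 57853063), fell from 49.9 ± 1.85 to 2.83 ± 0.614 CPM, a log2 fold change of -4.11 ± 0.11 (edgeR adjusted p = 1.43e-18). The hormone STC2 (-4.17 ± 0.53), the protease TMPRSS3 (-3.94 ± 0.49), the sodium channel SCN4A (-3.58 ± 0.27), the matricellular protein CTGF (-3.27 ± 0.088) and the transcriptional regulator IFRD1 (-3.22 ± 0.088) showed the other largest falls.

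NF-kB targets and chemokines were higher with Neisseria in 26 of 34 cases and lower in 0, with a median log2 fold change of 1.30 (1.02 with bounds), a camera adjusted p of 2.38e-22 and an adjusted p of 0.0272 with an estimated correlation. IL8 rose from 8.02 ± 0.855 to 44.1 ± 6.14 CPM (2.48 ± 0.11), TNFAIP3 by 2.37 ± 0.10, RELB by 2.11 ± 0.070 and NFKB2 by 1.46 ± 0.062. Heat shock genes rose in 13 of 14 cases and fell in 0, with a median of 0.91, a camera adjusted p of 4.83e-27 and an adjusted p of 0.0243 with an estimated correlation. The constitutive chaperone HSPA8 rose from 833 ± 2.58 to 2892 ± 79.7 CPM (1.79 ± 0.051), HSPH1 by 1.12 ± 0.047 and HSP90AA1 by 1.16 ± 0.055, while HSPA1B (1.25 ± 0.053) shares nearly identical sequence with HSPA1A and its own change is uncertain. Cholesterol biosynthesis genes were up in 19 of 21 cases and down in 1, with a median of 0.88, including HMGCS1 (2.01 ± 0.064), INSIG1 (1.48 ± 0.058) and SQLE (1.02 ± 0.051). The camera adjusted p was 1.21e-28, and the adjusted p was 0.0587 with an estimated correlation. Glycolysis genes were up in 13 of 16 cases and down in 3, with LDHA at 1.64 ± 0.055, PGK1 at 1.35 ± 0.057 and ENO1 at 1.17 ± 0.058 (camera adjusted p = 1.01e-13, adjusted p = 0.153 with an estimated correlation). The lists of NRF2 genes (14 of 18 up and 2 down, NQO1 0.67 ± 0.049) and matrix and transition genes (8 of 19 up and 3 down) passed as higher. So did gastric and mucin genes (8 of 15 up and 1 down, TFF1 2.06 ± 0.17), G2/M genes (14 of 21 up and 3 down, BUB1B 0.55 ± 0.068) and hypoxia targets (8 of 21 up and 6 down, PGK1 and LDHA among the higher and STC2 among the lower). Their camera adjusted p values were 9.30e-04, 4.72e-04, 0.00289, 0.0286 and 0.0464 in that order. With an estimated correlation the adjusted p values were 0.153, 0.371, 0.277, 0.430 and 0.188. Adhesion receptors passed as higher (5 of 11 up and 2 down, camera adjusted p = 0.0121, adjusted p = 0.355 with an estimated correlation), with a median of 0.042 that turned to -0.038 when scaled by library size only.

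The list of ATF4 pathway and unfolded protein response genes fell with Neisseria, 16 of 23 down and 3 up, with a median of -1.28, a camera adjusted p of 1.84e-32 and an adjusted p of 0.0266 with an estimated correlation. Without 7 endoplasmic reticulum chaperones, 14 of 16 were down and 0 up, with a median of -1.62. A fall of such chaperones was not shown: in a list written later 4 of 12 were up and 2 down, with a median of 0.054. Asparagine synthetase ASNS fell from 678 ± 21.6 to 190 ± 15.7 CPM (-1.84 ± 0.061). The cystathionine lyase CTH (-1.98 ± 0.073), the serine synthesis enzyme PSAT1 (-1.55 ± 0.059) and the cystine transporter SLC7A11 (-1.68 ± 0.068) fell too. Immediate-early genes fell in 16 of 28 cases and rose in 1, with a median of -0.32, a camera adjusted p of 1.59e-11 and an adjusted p of 0.0280 with an estimated correlation, for example EGR1 (-1.89 ± 0.074), FOSB (-2.80 ± 0.17) and IER2 (-0.78 ± 0.052). Wnt/beta-catenin targets were lower in 12 of 14 cases and higher in 0, with a camera adjusted p of 7.00e-10 and an adjusted p of 0.0266 with an estimated correlation, among them NKD1 (-1.99 ± 0.063), BAMBI (-1.13 ± 0.050) and EPHB3 (-1.10 ± 0.083). Targets of TGF-beta and BMP (6 of 11 down and 1 up, SKIL -1.17 ± 0.074 and SMAD7 -0.85 ± 0.099), MAPK feedback genes (11 of 21 down and 6 up, DUSP6 -1.80 ± 0.060 and DUSP4 1.14 ± 0.052) and mitochondrially encoded mRNAs (9 of 13 down) were lower as well. These had camera adjusted p values of 3.08e-04, 0.0238 and 0.0215, and adjusted p values of 0.0587, 0.153 and 0.397 with an estimated correlation.

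Leukocyte markers passed as higher with Neisseria, 5 of 6 up, with LCP1 at 1.02 ± 0.16 and CD68 at 1.10 ± 0.20 (camera adjusted p = 0.0419, adjusted p = 0.191 with an estimated correlation). Of 5 fibroblast markers 2 fell and 1 rose (camera adjusted p = 0.178), with PDGFRA at -1.07 ± 0.070 and COL1A1 at 0.62 ± 0.078, and the endothelial marker ESAM rose by 0.38 ± 0.11 while VWF stood at 0.70 ± 0.38 without passing. Of the 4 tested metallothionein genes 3 rose, MT2A by 1.35 ± 0.089. The other lists did not pass (lowest camera adjusted p 0.0943, highest 0.677). Of these, 10 of 25 interferon-stimulated genes were down and 4 up, 8 of 21 p53 targets down and 3 up, and 6 of 22 G1/S genes down and 3 up. Likewise 13 of 25 actin genes were up and 8 down, 6 of 20 junction genes up and 7 down, and 7 of 18 apoptosis genes up and 5 down. Finally 5 of 13 pattern recognition receptors were up and 0 down, 4 of 8 antimicrobial genes up and 0 down, 10 of 30 ribosomal proteins up and 0 down, and 3 of 12 histones up and 2 down. The junction list had a median of 0.013 and a mean of -0.066, opposite in sign. Adjusted over the list alone, the counts differed for NF-kB targets (27 up), immediate-early genes (2 up and 17 down), interferon-stimulated genes (11 down), ATF4 genes (17 down), NRF2 genes (3 down), TGF-beta targets (2 up), gastric genes (9 up and 2 down), pattern recognition receptors (3 up), adhesion receptors (3 down) and mitochondrial mRNAs (11 down), and were the same for the others. In all 6596 of 13756 genes changed, 3392 higher and 3204 lower (edgeR adjusted p under 0.05), and 824 changed at least 2-fold, 421 higher and 403 lower. Scaled by library size only, the calls were 2561 higher and 4188 lower, and 5 of the 17 lists that passed also passed with an estimated correlation.

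**Figure D2:**
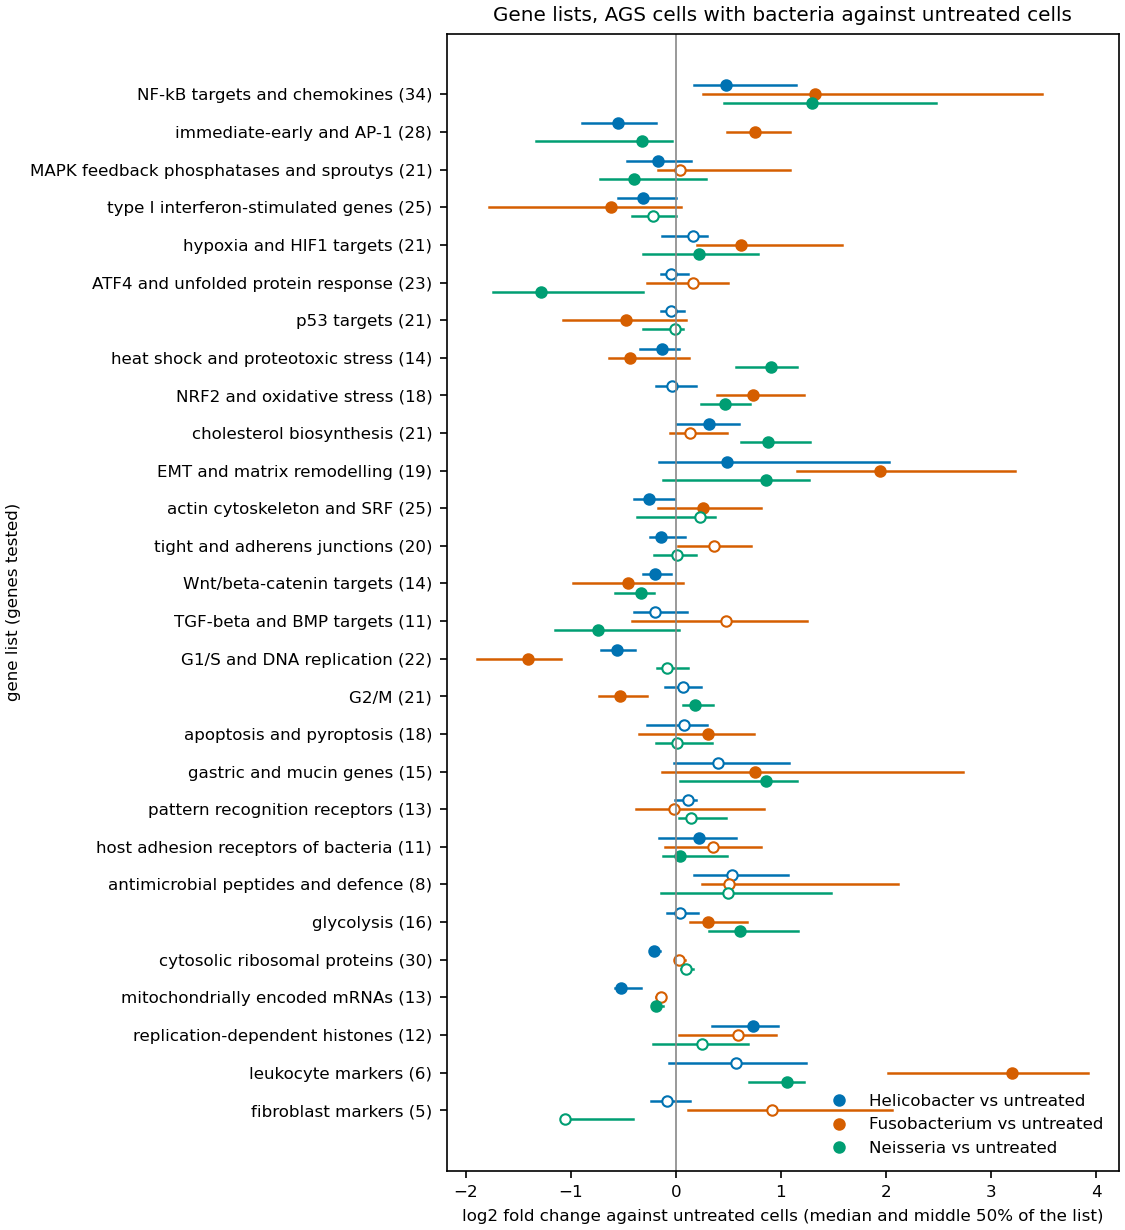
Log2 fold change against untreated cells (horizontal axis) of the gene lists with at least 5 tested genes (vertical axis, number tested in brackets) for each bacterium. Points are list medians, lines span the middle 50% of the genes, and filled points passed the camera test at an adjusted p under 0.05, such as the ATF4 list with Neisseria at -1.28 and the G1/S list with Fusobacterium at -1.41.

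**Figure D3:**
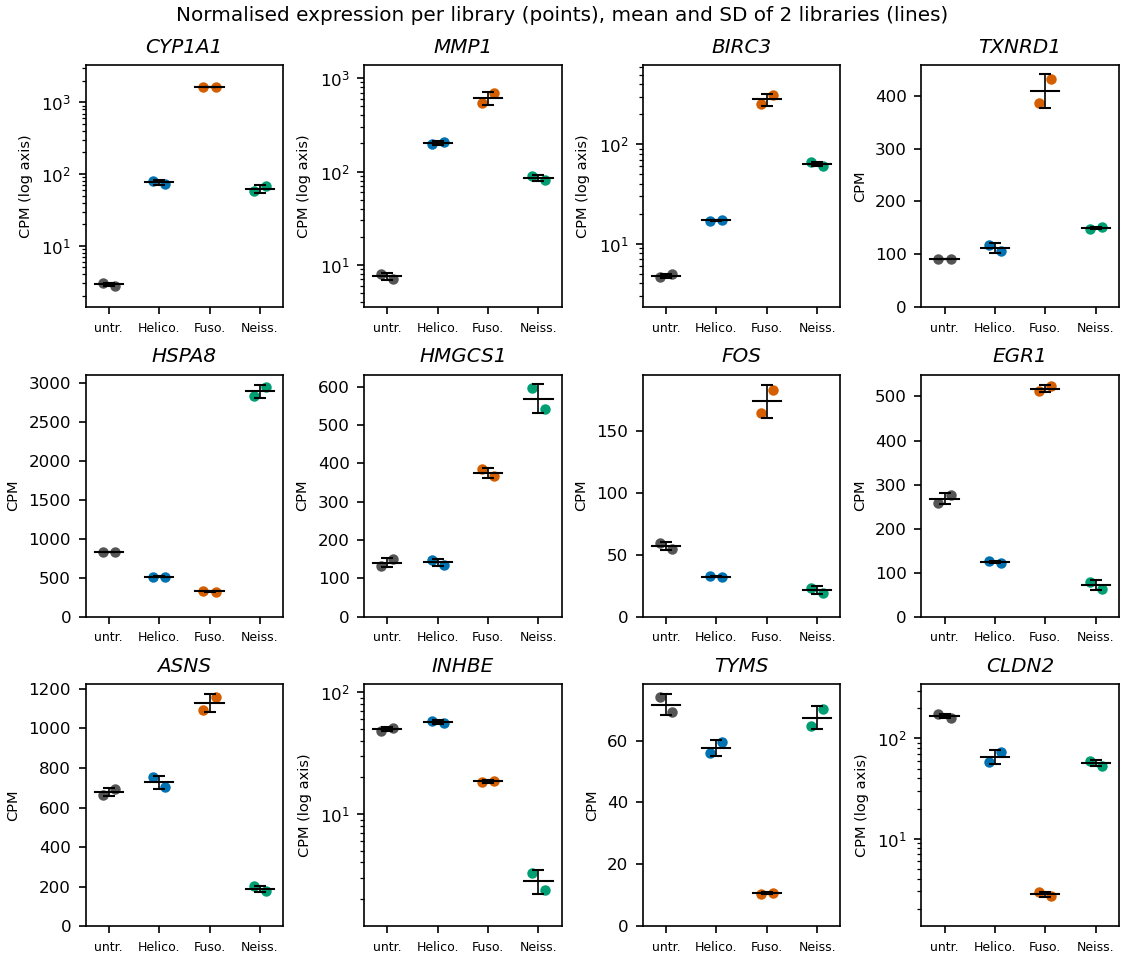
CPM per library (points) with the mean and SD of the 2 libraries of each group (lines) for 12 genes, on a logarithmic vertical axis for CYP1A1, MMP1, BIRC3, INHBE and CLDN2 and a linear axis from 0 for the others. CYP1A1 lies at 2.88 ± 0.147 CPM in untreated cells and 1644 ± 9.24 CPM with Fusobacterium, and INHBE at 49.9 ± 1.85 CPM in untreated cells and 2.83 ± 0.614 CPM with Neisseria.

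Helicobacter and Fusobacterium differed in immediate-early genes. Immediate-early and AP-1 genes were lower with Helicobacter in 25 of 28 cases and higher in 1, with a median log2 difference of -1.26, a camera adjusted p of 6.01e-19 and an adjusted p of 0.0304 with an estimated correlation. Of the 19 lists that passed camera here, no other passed with an estimated correlation. FOS differed by -2.42 ± 0.073 (SE) and NR4A1 by -2.09 ± 0.076. NF-kB targets were lower with Helicobacter in 20 of 34 cases and higher in 6 (camera adjusted p = 1.71e-07, adjusted p = 0.0623 with an estimated correlation), with IL8 at -3.76 ± 0.095. G1/S genes were higher with Helicobacter in 19 of 22 cases (camera adjusted p = 8.98e-11, adjusted p = 0.0623 with an estimated correlation), NRF2 genes lower in 15 of 18 (camera adjusted p = 2.80e-09, adjusted p = 0.0648 with an estimated correlation) and leukocyte markers lower in 4 of 6 (camera adjusted p = 2.55e-06, adjusted p = 0.0623 with an estimated correlation). CLDN2 was higher with Helicobacter by 4.54 ± 0.16, PTPRO by 3.92 ± 0.56, the myosin MYH13 by 3.51 ± 0.25, the channel subunit CNGB3 by 3.45 ± 0.37 and, with the same uncertainty as before, MRPL30 by 3.81 ± 1.1. With 0 counts in both Helicobacter libraries, NOVA2 was at least 77.4-fold lower than with Fusobacterium, DLX3 at least 36.4-fold, SHANK1 at least 28.2-fold, OLFM1 at least 23.8-fold and RTBDN at least 23.3-fold. Adjusted over the list alone, the counts of these 5 lists differed for NF-kB targets (21 down) and immediate-early genes (26 down). In all 9594 genes differed, 4928 higher and 4666 lower with Helicobacter, 2536 of them at least 2-fold (855 higher and 1681 lower). Scaled by library size only, which moved the median of all genes by 0.136 on the log2 scale, the calls were 6092 higher and 3752 lower.

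Helicobacter and Neisseria differed in ATF4 pathway and heat shock genes. Of 13 lists that passed camera, 2 also passed with an estimated correlation. Genes of the ATF4 pathway were higher with Helicobacter in 16 of 23 cases and lower in 4, with a median of 0.89, a camera adjusted p of 8.59e-35 and an adjusted p of 0.0249 with an estimated correlation. STC2 differed by 4.73 ± 0.47, INHBE by 4.30 ± 0.11 (edgeR adjusted p = 5.98e-19), SCN4A by 4.16 ± 0.24, the glucocorticoid-induced TSC22D3 by 4.00 ± 0.35 and the stress factor DDIT3 by 3.05 ± 0.11. C12orf39 had 75 counts with Helicobacter against 2 with Neisseria, a ratio of 33.5 with an exact 95% interval of 8.96 to 282. All 14 heat shock genes were lower with Helicobacter, with a median of -0.91, a camera adjusted p of 1.04e-42 and an adjusted p of 0.00733 with an estimated correlation. NF-kB targets were lower with Helicobacter in 22 of 34 cases (camera adjusted p = 2.87e-11, adjusted p = 0.0759 with an estimated correlation), including CXCL5 (-5.14 ± 0.37), and cholesterol biosynthesis genes in 17 of 21 (camera adjusted p = 9.23e-15, adjusted p = 0.167 with an estimated correlation). The aldo-keto reductase AKR1C1 (-3.26 ± 0.34), which has near-identical relatives, and the zinc finger factor ZFPM2 (-2.95 ± 0.55) were lower too. The readthrough genes CORO7-PAM16, at least 30.5-fold lower with 0 counts in both Helicobacter libraries, and UBE2F-SCLY (-2.92 ± 0.66) overlap their parent genes and are uncertain. The counts adjusted over the list alone were the same for these 4 lists. In all 6478 genes differed, 3177 higher and 3301 lower with Helicobacter, and 609 differed at least 2-fold (410 higher and 199 lower). Scaled by library size only, which moved the median of all genes by 0.130, the calls were 4901 higher and 2082 lower.

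Fusobacterium and Neisseria differed in immediate-early, heat shock and G1/S genes. Immediate-early genes were higher with Fusobacterium in 24 of 28 cases and lower in 1 (median 1.16, camera adjusted p = 1.13e-20), heat shock genes lower in 13 of 14 (camera adjusted p = 2.35e-19) and G1/S genes lower in all 22 (median -1.38, camera adjusted p = 2.69e-24). Of 14 lists that passed, these 3 also passed with an adjusted p of 0.0105 with an estimated correlation. CTGF differed by 3.40 ± 0.087, FOS by 3.01 ± 0.079, HSPA8 by -3.15 ± 0.055, RRM2, a subunit of ribonucleotide reductase, by -2.16 ± 0.067 and TYMS by -2.66 ± 0.083. ATF4 pathway genes were higher with Fusobacterium in 17 of 23 cases and lower in 5 (camera adjusted p = 2.72e-13, adjusted p = 0.0666 with an estimated correlation), with ASNS at 2.57 ± 0.061. NF-kB targets were higher in 17 and lower in 13 of 34 cases and did not pass as a list (camera adjusted p = 0.146). Within it CXCL5 was lower with Fusobacterium (-4.71 ± 0.36), as was LTB (-4.15 ± 0.52), while IL8 was higher (1.43 ± 0.074). UBD (-4.18 ± 0.22) and CLDN2 (-4.32 ± 0.17) were lower with Fusobacterium, as was the readthrough gene CORO7-PAM16, with 0 counts in both Fusobacterium libraries and at least 26.4-fold lower. With 0 counts in both Neisseria libraries, NOVA2 was at least 68.0-fold higher with Fusobacterium, LRRC15 at least 23.7-fold, SH2D1B at least 15.4-fold, NEURL1 at least 13.7-fold and TMEM63C at least 13.4-fold. The counts adjusted over the list alone were the same for these 5 lists. In all 9421 genes differed, 4731 higher and 4690 lower with Fusobacterium, and 2588 differed at least 2-fold (1815 higher and 773 lower). Scaled by library size only, the calls were 4683 higher and 4738 lower.

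Changes against untreated cells were also compared across the bacteria. In all 3 comparisons with untreated cells 863 genes rose and 761 fell, where independent lists of these sizes would share 210 and 197. Among the genes that rose with every bacterium were CYP1A1, TNFRSF9, S100A3, MMP1, MMP7 (log2 fold changes of 3.33 with Helicobacter, 4.37 with Fusobacterium and 3.29 with Neisseria) and BIRC3 (1.84, 5.88 and 3.72 in that order). Among those that fell were OAS2, PTPRO, CLDN2 (-1.35, -5.88 and -1.56) and FOSB (-2.51, -0.83 and -2.80). Helicobacter and Fusobacterium shared 1353 higher and 1389 lower genes (850 and 847 for independent lists), with 971 changed in opposite directions. Helicobacter and Neisseria shared 1300 and 1120 (613 and 560 for independent lists), with 659 opposite, and Fusobacterium and Neisseria 1800 and 1883 (1160 and 1129 for independent lists), with 1386 opposite. The correlation of log2 fold changes across genes, which are not independent replicates, was 0.454 for Helicobacter and Fusobacterium, 0.533 for Helicobacter and Neisseria and 0.462 for Fusobacterium and Neisseria. The shared untreated libraries alone gave 0.507, 0.511 and 0.499 in 20 simulations without any effect. The share of genes with the same sign was 61.1%, 63.7% and 61.8% in the same order, below the 66.9%, 66.8% and 66.5% simulated. The covariance was 0.335, 0.233 and 0.426 in the same order, against 0.0213, 0.0216 and 0.0216 simulated, differences of 0.314, 0.211 and 0.405. With the controls split, so that 1 bacterium was set against untreated replicate 1 and the other against untreated replicate 2 (chosen after the data were seen), the covariance was 0.353 or 0.327 for Helicobacter and Fusobacterium, 0.174 or 0.180 for Helicobacter and Neisseria and 0.414 or 0.448 for Fusobacterium and Neisseria. The correlations were 0.319 or 0.307, 0.251 or 0.268 and 0.333 or 0.355. With split controls Helicobacter and Fusobacterium shared 845 or 920 higher and 892 or 1010 lower genes (476 or 523 and 508 or 573 for independent lists). Helicobacter and Neisseria shared 774 or 818 and 655 or 726 (307 or 330 and 299 or 313), and Fusobacterium and Neisseria 1363 or 1341 and 1433 or 1364 (832 or 812 and 827 or 769). Opposite changes numbered 560 or 622, 347 or 354 and 1034 or 969 in the order above.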

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

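This value was chosen for testing only after the deposited columns had been seen. The library totals that the authors divided by to make RPKM exceed the gene counts in every library, and they did so most with Fusobacterium, by 7.90% of the gene counts on average (7.72% and 8.08% in the 2 libraries). The untreated libraries, which serve as the control here, had 5.77% and 5.15%, the Helicobacter libraries 5.68% and 5.22%, and the Neisseria libraries at most 5.53%. The columns behind this value were not used in any comparison, and the file does not say what the additional reads are.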

How the results depend on the processing

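All alternatives were set before the data were examined except the fit of the 6 treated libraries without a block, the replicate block with all 8 libraries and the split controls, which were chosen after. No named gene with a call changed its direction under any alternative that was run. The numbers of changed genes stayed within 1.5 times their values under each scaling, test and filter that was run. The DESeq2 Wald test gave the lowest of these with the Helicobacter, Neisseria and Helicobacter against Neisseria comparisons at 3525, 5262 and 5096 genes. With a minimum of 2-fold besides the threshold, the counts were 388 (Helicobacter), 2801 (Fusobacterium) and 824 (Neisseria) against untreated cells. Between bacteria they were 2536 (Helicobacter and Fusobacterium), 609 (Helicobacter and Neisseria) and 2588 (Fusobacterium and Neisseria), fewer by the construction of this alternative. Leaving out 1 library at a time, where the lone library of a group is assumed to vary like the other groups, gave 3147 to 3600 genes for Helicobacter against untreated cells, 8628 to 9148 for Fusobacterium and 5074 to 5619 for Neisseria. The 3147 genes, without untreated replicate 2, rest on fewer samples. Between bacteria the ranges were 8737 to 9190, 5057 to 5576 and 8527 to 8949 in the order above.

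With the replicate block between bacteria the counts were 9482, 6294 and 9311, against 9515, 6344 and 9349 for the same 6 treated libraries without it. Replicate 2 is in every group, so a replicate block could also be fitted to all 8 libraries, and it gave 3033 genes for Helicobacter, 8499 for Fusobacterium and 5122 for Neisseria against untreated cells. That fit has 2 residual degrees of freedom and uses untreated replicate 2 alone for the level of untreated cells, since no treated library is numbered 1. Of 28 lists camera with an estimated correlation passed 0 (Helicobacter), 5 (Fusobacterium) and 5 (Neisseria) against untreated cells and 1, 2 and 3 between bacteria in the order above. The fry test passed 25 with Fusobacterium, 24 between Helicobacter and Neisseria and 23 between Fusobacterium and Neisseria. It compares a list with no change and camera compares it with the other genes. The numbers of genes with shared calls stayed within 1.5 times their values scaled by library size only and among genes with a mean of at least 5 CPM. With split controls, which leave 1 untreated library for each bacterium, the overlap of responses to the bacteria was lower. For Helicobacter and Fusobacterium it was 1737 genes (Helicobacter against untreated 1) or 1930, and for Helicobacter and Neisseria 1429 or 1544. For Fusobacterium and Neisseria it was 2796 or 2705, within 1.5 times its value. Of the values for named genes and comparisons, 22 lost their call with the replicate block of 8 libraries, 14 without Helicobacter replicate 2, 13 without Neisseria replicate 2, 13 without untreated replicate 2, 12 without untreated replicate 1, 13 with the DESeq2 Wald test and 10 scaled by library size only, and fewer in the others counted, all with the same direction. Losses to the 2-fold minimum were not counted. Unique or estimated counts and other pseudocounts were not run, since the file holds total counts. Depth limits the genes at 0 counts to lower bounds, and 8128 genes with a count were too low to be tested.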

Other observations

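All tests in this part were chosen only after the results were seen, except the correction for gene length and GC content. Lists written after the values had been seen describe further groups. Except in the transporter and synthetase list and the chaperone list, tests leave out the genes whose changes were known when the list was written. The transporter and synthetase list leaves out only the gene shared with the ATF4 list, and the chaperone list leaves out none. The cornified envelope and squamous keratin list, genes of stratified epithelia, had 9 of 18 members up and 4 down with Helicobacter (median log2 fold change 1.82), 13 up and 3 down with Fusobacterium (2.32) and 11 up and 3 down with Neisseria (1.51). Over the 11 genes left without 7 known ones, 2 were up and 4 down with Helicobacter, 6 up and 3 down with Fusobacterium and 4 up and 3 down with Neisseria (camera adjusted p = 0.541, 8.20e-04 and 0.156, adjusted p = 0.753, 0.319 and 0.369 with an estimated correlation). A change of the group beyond the known genes was therefore not shown for Helicobacter and Neisseria. With Fusobacterium it passed only with the preset correlation and was not decided. KRT13 rose by 1.56 ± 0.069, 4.75 ± 0.067 and 1.61 ± 0.069 in that order (SE), and KRT6A, which has a near-identical relative, by 4.04 ± 0.098, 2.16 ± 0.12 and 2.86 ± 0.11. Targets of the aryl hydrocarbon receptor were up in 4, 3 and 4 of 7 cases and down in 0, 3 and 1. Without CYP1A1, the known gene with by far the largest change, the list did not pass (camera adjusted p = 0.227, 0.212 and 0.216, adjusted p = 0.621, 0.491 and 0.369 with an estimated correlation). TIPARP rose by 0.69 ± 0.081 with Helicobacter and 1.74 ± 0.075 with Fusobacterium, and ALDH3A1 fell with Fusobacterium (-0.63 ± 0.073).

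Hosts of small nucleolar RNAs and substrates of nonsense-mediated decay were down in 14 and up in 1 of 20 cases with Neisseria, with IFRD1 at -3.22 ± 0.088 and SNHG7 at -1.87 ± 0.10. Over the 15 genes left without 5 known ones, 9 were down and 1 up with Neisseria (camera adjusted p = 4.70e-04, adjusted p = 0.0855 with an estimated correlation), 3 up and 2 down with Helicobacter (camera adjusted p = 0.930) and 4 up and 5 down with Fusobacterium (camera adjusted p = 0.212). Adjusted over the list alone, the counts of these added lists differed for the cornified list (5 down with Helicobacter, 12 up with Neisseria), receptor targets (1 down with Helicobacter), the decay list (7 up with Fusobacterium) and the transporter and synthetase list (1 down with Helicobacter).

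Genes without counts in untreated cells were read in the Fusobacterium libraries. Genomic DNA would have raised olfactory receptor genes with them, but 349 of these had 40 counts (exact 95% interval 28.6 to 54.5), where 471 would follow from the gain per kilobase of the other genes. Reads beyond the gene counts, which would go with such DNA, were highest in these libraries (7.72% and 8.08%, at most 5.77% in the others), so DNA is argued against as the whole cause of the counts in these genes and not as a source of other reads. Leukocytes would bring PTPRC, TYROBP, FCER1G and CD14, whose summed CPM was at most 0.929% of that of CORO1A in either library (68.3 and 64.2 CPM), and depth is argued against by libraries thinned to 17167078 counts, where 59 and 67 of 4757 such coding genes had at least 10 counts with Fusobacterium and at most 7 in the other treated libraries, a lowest ratio of 8.43. A list of marker genes of histone deacetylase inhibitors was, without 4 known genes, up in 2, 5 and 5 of 6 cases and down in 0, 1 and 1 with Helicobacter, Fusobacterium and Neisseria. It did not pass (camera adjusted p = 0.250, 0.135 and 0.156, adjusted p = 0.621, 0.403 and 0.342 with an estimated correlation). A response to such an inhibitor therefore cannot be told apart from other responses to Fusobacterium.

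Part of the change against untreated cells was common to the 3 bacteria. Chance values of the shared untreated libraries are argued against as the whole cause by the covariance of log2 fold changes. It was at least 0.233, where simulations without an effect gave a mean of at most 0.0216. With the controls split so that no untreated library was shared, it was at least 0.174. The share of genes with the same sign, 61.1% to 63.7%, was below the simulated 66.5% to 66.9% and does not add to this. Handling of the untreated cells apart from the bacteria might give the same changes, and 1624 genes had the same call in all 3 comparisons. Without a mock treatment, this cannot be told apart from a common response to bacteria.

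ATF4 pathway genes were lower and heat shock genes higher with Neisseria. Bias by gene length or GC content is argued against, since the ATF4 list median was -1.28 before and -1.30 after a correction, and the heat shock median 0.91 before and 0.81 after. Release from endoplasmic reticulum stress was tested only in a form that lowers the chaperones of that compartment like the ATF4 list. The median of the chaperone list was 0.054 (-0.026 scaled by library size only), against -1.28 for the ATF4 list. Over its 12 genes, of which 4 were up and 2 down, the SD was 0.418. The chaperone list shares 7 of its 12 genes with the ATF4 list, whose values had been seen when the chaperone list was written. The contrast of the 2 medians was therefore partly fixed in advance, and no conclusion is drawn from it. A release that leaves the chaperones unchanged cannot be excluded by these values. Amino acid transporters and aminoacyl-tRNA synthetases outside the ATF4 list were down in 20 of 20 cases (camera adjusted p = 6.27e-27, adjusted p = 0.0855 with an estimated correlation), against 8 up and 0 down with Helicobacter and 2 up and 12 down with Fusobacterium. With the gene shared with the ATF4 list, 21 of 21 were down and camera with an estimated correlation passed (adjusted p = 0.0314). Its unadjusted p was 0.0157 with that gene and 0.0225 without it. The adjusted values also differ because the other added lists were adjusted with or without their known genes. The ATF4 list without the 7 genes shared with the chaperone list was down in 14 and up in 0 of 16 cases (median -1.62, adjusted p = 0.0169 with an estimated correlation). With the transporters and synthetases outside the ATF4 list short of passing with an estimated correlation, a lower activity of ATF4 cannot be told apart from other causes, and it says nothing of the heat shock genes.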
